A study of Canis lupus familiaris with 6 samples.

How the data were processed

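RNA from the left ventricle of 6 dogs was measured on Affymetrix canine arrays, 1 array per dog, after a standard 1-cycle biotin labelling, per the labels' protocols. The control group held 3 dogs of 3 breeds and the affected group held 3 Great Danes with cardiomyopathy. The labels call the arrays biological replicates, and each array was taken as 1 animal. Each group had 1 female and 2 males.

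The deposited values were used on the log2 scale. The submitters' processing notes name GCRMA and MAS5, with no role, order or version, and the log2 scale was inferred from these names and from the range of the values. The median of every probe set over the 6 arrays was 0 in all 43035 probe sets of the deposited table (largest absolute median 5e-07), so the deposited values hold differences between arrays and no expression level. Whether a gene was strongly or weakly expressed could therefore not be read from them, and no genome build is given in the sources used here, so no coordinates are printed. For arrays, precision is limited by their number, 3 per group.

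The plan made before the data were examined was to leave out the 40% of probe sets with the lowest mean level and to let the variance prior follow the level. Neither was possible with values centred per probe set. After the values were seen, the filter was replaced by leaving out the 40% of probe sets with the smallest range over the 6 arrays (without regard to group), which kept ranges of 0.351 and above on the log2 scale, and the variance prior was fitted without a trend. A filter on range takes probe sets by their variability and can affect the p-values of the fit. In the same way a gene's value became the mean of all its tested probe sets, in place of the probe set with the highest level. A pseudocount of 32 was planned as an alternative and was not run, since the values have no linear level to add it to. The 111 control probe sets were left out of the tests, which left 42924 probe sets before the filter and 25754 after it. In the annotation table of the array, 29254 probe sets had 1 gene symbol, 439 had several and 13231 were not listed. Of the tested probe sets, 18469 had 1 symbol, for 10277 genes, and only these were named.

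Affected and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only factor, two-sided, 4 residual degrees of freedom and 3.01 prior degrees of freedom), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. A looser criterion counted probe sets at an unadjusted p under 0.05 and at least 2-fold; it has no control of false calls. Fold changes are affected minus control on the log2 scale, given with the moderated standard error (SE). Gene lists (33) and cell type marker lists (19) fixed before the data were examined were tested on gene values with camera, with a preset correlation of 0.01 between genes, where at least 5 genes were measured; camera compares a list with all other genes. The list tests were repeated with an estimated correlation and with fry. Statements that a member passed "adjusted over the list alone" use the Benjamini-Hochberg adjustment within that list.

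The rule for named genes, also fixed before the data were examined, took per direction up to 12 symbols with the largest change among probe sets past the adjusted threshold whose affected and control values did not overlap, 1 probe set per symbol, without uncharacterised symbols. Where fewer passed, the remainder came from probe sets at an unadjusted p under 0.05 and at least 2-fold without overlap, ranked by size. It added TRDN and FKBP1B, which the study's paper is remembered to have reported from these arrays and which are therefore not independent evidence, the heart failure genes NPPA, NPPB, MYH6, MYH7, ATP2A2, PLN, RYR2 and CASQ2, up to 4 members of each list with the smallest p, and XIST and Y-linked genes as a check of the recorded sexes. RNA integrity was compared as the difference between 3' and 5' control probe sets of beta-actin and GAPDH with an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1.

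The steps were tested on simulated arrays for the comparison of affected with control. With 200 changed among 42924 simulated probe sets, 25754 of them tested, the share recovered at the adjusted threshold was 64% at a log2 change of 1, 90% at 2, 98% at 3 and 100% at 4, with 50 probe sets per size. In 20 simulated sets of unchanged arrays, no probe set was called and at most 297 met the looser criterion. A gene list was called in 1 of these 20 sets with the preset correlation, and in 0 with an estimated one. A matrix list raised by 0.5 on the log2 scale was called in 20 of 20 sets with the preset correlation and in 15 with an estimated one. The simulated genes were independent of each other, unlike those of a tissue. The changed probe sets were drawn at random from all, each with its own fitted spread. The shares recovered therefore do not hold for probe sets that vary more than most. In the data FKBP1B at 6.57 (SE 1.18) did not pass the adjusted threshold (limma adjusted p = 0.285).

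Alternatives fixed before the data were examined were no filter, the upper 50% by range, quantile normalization, median centring of each array, array weights, the replicate number as a block, sex or age as a covariate, leaving out each array, and for lists an estimated correlation and fry. Alternatives chosen after seeing the data were a variance trend on the row mean, a range of at least 1, a term for the arrays affected 1 and affected 3 (whose spiked control transcripts stood apart), affected 2 against the controls only, and the probe set with the largest range per gene.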

Results

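Left ventricular RNA of 6 dogs was measured on 1 array each, with 25754 probe sets tested. The controls were a Labrador retriever of 12 years (control 1), a St. Bernard of 10 years (control 2) and a Greater Swiss Mountain dog of 4 years (control 3). The affected dogs were Great Danes with cardiomyopathy, aged 9 years (affected 1) and 7 years (affected 2 and affected 3). Breed and disease therefore went together, and no comparison here separates them. Control 2 and affected 1 were the females, so leaving out either array left its group with males only. Each value is a log2 difference from the probe set's own median over the 6 arrays, so levels of different genes could not be compared. All group values below are from n = 3 dogs against n = 3 dogs.

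The comparison of affected with control hearts asked which transcripts differ in the left ventricle of Great Danes with the disease. EPYC, which encodes epiphycan, a small leucine-rich proteoglycan of cartilage matrix, rose in affected hearts by 3.61 on the log2 scale (SE 0.27), or 12.2-fold, and was higher in each of the 3 affected arrays than in any control. Such a lack of overlap was common, in 32.5% of all tested probe sets, where 10% would be expected by chance. The control probe sets of unexpressed tags did not overlap either, and 18.6% of tested probe sets followed them at a correlation over 0.9. The excess over 10% was therefore not told apart from a background offset. EPYC was the only named gene past the adjusted threshold (limma, adjusted p = 0.0178). Another 5 probe sets without a gene symbol in the annotation also rose, by between 2.74 (SE 0.25, limma adjusted p = 0.0481) and 5.63 (SE 0.34, limma adjusted p = 0.00632). No probe set fell at this threshold in limma, while at an unadjusted p under 0.05 there were 1757 higher and 771 lower probe sets, where 1288 in all would be expected by chance. These counts depended on single arrays. They were 982 and 326 without affected 3, near the number expected by chance, 1153 and 335 without affected 1, and 2877 and 2274 without control 2. Without the filter on range there were 1945 higher and 2713 lower at that unadjusted p in limma, so the excess of higher ones turned. Of these, 790 of the lower and 33 of the higher were among the probe sets that the filter left out. The other 1923 lower and 1912 higher were among those it kept, so the excess of higher ones was lost there too. Of all probe sets that the filter left out, 76.6% followed the unexpressed tags at a correlation over 0.9. EPYC kept a log2 change between 3.33 and 4.09 but had a limma adjusted p of 0.0516 to 0.329 in 10 alternatives. It was 0.193 without the filter, 0.167 after quantile normalization, where 0 probe sets were called in all, 0.0516 with sex and 0.0728 with age. It was 0.0613, 0.0797, 0.329 and 0.0615 without control 1, control 2, control 3 and affected 3. It was 0.0798 with a term for affected 1 and affected 3 and 0.151 for affected 2 alone, which both estimated the same contrast (4.09) of 1 affected dog with the 3 controls.

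By the looser criterion 663 probe sets were higher and 198 lower in affected hearts, a share of 77.0% higher, which was 66.1% after quantile normalization (484 higher and 248 lower). The named genes chosen from this group did not pass the adjusted threshold. With only probe sets whose range was at least 1, a filter chosen after seeing the data, 18 of the named genes passed (limma adjusted p from 8.95e-05 to 0.0461). Among the higher ones, the secreted complement component C6 differed by 4.96 (SE 0.57, limma adjusted p = 0.113, and 0.0362 in the upper 50% by range) and all 3 of its probe sets were higher. CILP, a matrix protein of cartilage, differed by 4.25 (SE 0.70), the adhesion molecule CDH11 (cadherin 11) by 3.29 (SE 0.37) in one probe set (limma adjusted p = 0.0362 in the upper 50% by range) and 0.68 in the other, and POSTN, the matricellular protein periostin, by 2.93 (SE 0.81). The muscle genes CASQ1, the skeletal muscle calsequestrin, and MYOT, the Z-disc protein myotilin, were higher by 3.57 (SE 1.14) and 3.17 (SE 0.88). The other higher genes were IGSF1 at 4.44, FAM184B at 2.95 in one probe set and 0.08 in the other, and DKK2, a secreted Wnt modulator, at 2.92. TNFRSF1B was 3.32 higher in one of its probe sets and -1.50 in the other. For affected 2 against the controls alone POSTN differed by 0.95, MYOT by 1.60 and DKK2 by 1.64, and without control 2 DKK2 differed by 1.92.

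Among the lower named genes, CXCL10, an interferon-induced chemokine, differed by -3.51 (SE 0.36, limma adjusted p = 0.0912), with both probe sets lower. CCBE1, a factor in lymphatic vessel growth, was lower by -3.71 (SE 1.06) in one probe set and -0.90 in the other, KIF23, a kinesin of cytokinesis, by -3.65 (SE 0.55) and STRAP by -3.42 (SE 0.80). Values for the remaining lower genes were -2.93 for DPP6, -2.84 for PIP5K1B, -2.71 for the neutrophil and monocyte protein S100A9, -2.62 for PHLDA1, -2.58 for the transcription factor IRX3, -2.48 for FGF13 and -2.34 for the purine receptor P2RY1, where the smallest differences among the probe sets of FGF13 and P2RY1 were -0.42 and -0.63. None of these lower genes passed the adjusted threshold as reported, and CXCL10 passed in the upper 50% by range (limma adjusted p = 0.0269), with age (0.0398), without control 3 (0.0468) and with a variance trend (0.0434). DPP6 was at -1.58 without affected 1 and IRX3 at -1.50 without affected 3. For affected 2 against the controls alone STRAP was at -2.27, DPP6 at -0.68, FGF13 at -0.88 and P2RY1 at -1.34. Without control 3 the looser criterion gave 311 higher and 156 lower probe sets, a share of 66.6% higher. Control 3 stood apart, with 1683 tested probe sets below -1 against 161 to 510 on the other arrays. Without control 2 or affected 2 the looser criterion gave 1150 or 1011 higher and 367 or 363 lower ones.

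Triadin (TRDN), which anchors calsequestrin to the cardiac calcium release channel, was lower in affected hearts in 5 of its 9 probe sets by at least 1 on the log2 scale. These differed by -4.31 (SE 1.16), -4.14 (SE 0.97), -3.87 (SE 0.84), -3.71 (SE 0.57) and -1.30 (SE 0.32), and in each of them all affected values lay below all control values. Affected 3 was intermediate in the first 4, at -0.58, -0.70, -0.67 and -1.01, where affected 1 and affected 2 lay between -3.11 and -5.56. Another 3 probe sets differed by 0.07, 0.09 and -0.19, and the last by -0.83. FKBP1B (calstabin 2), a regulatory subunit of the same channel, was higher in both of its probe sets, by 6.57 (SE 1.18) and 3.34 (SE 0.61), without overlap between the groups. Groups did not overlap in 32.5% of all tested probe sets.

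**Figure D1:**
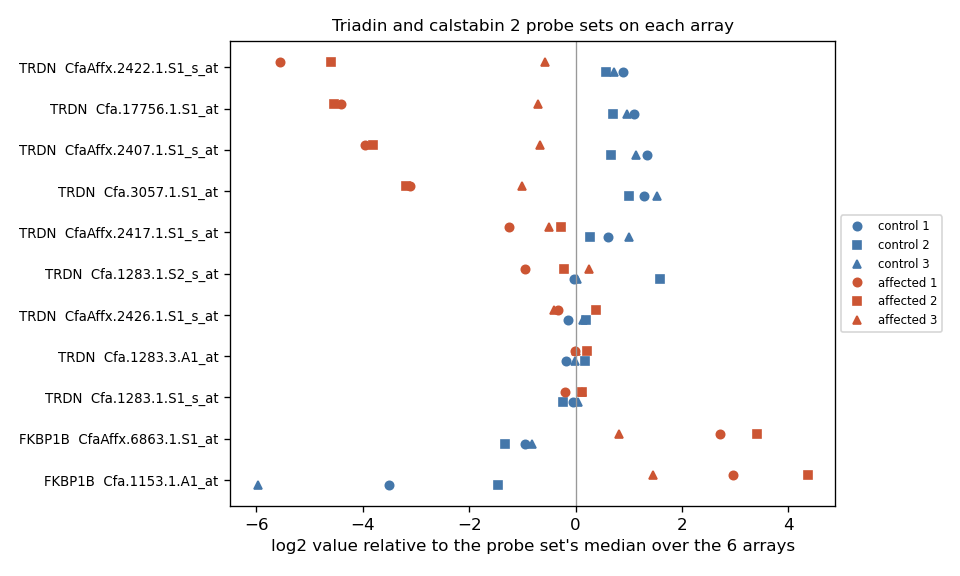
Log2 values of each TRDN (triadin) and FKBP1B (calstabin 2) probe set relative to its own median over the 6 arrays (horizontal axis), 1 symbol per array, controls in blue and affected in orange. The 5 upper TRDN probe sets separate the groups with affected 3 nearest to the controls in the first 4, 3 TRDN probe sets lie within 0.5 between groups, and both FKBP1B probe sets are higher in affected.

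Over all tested probe sets neither gene passed the adjusted threshold (limma adjusted p = 0.228 for the TRDN probe set with the smallest p and 0.285 for the larger FKBP1B one). Without affected 3 that TRDN probe set passed at -4.42 (limma adjusted p = 0.00576), and with a range of at least 1 TRDN and FKBP1B both passed (limma adjusted p = 0.00138 and 0.000503). Among the 22 calcium handling genes, FKBP1B was higher and TRDN lower adjusted over the list alone (limma adjusted p = 0.00611 and 0.0235 on the mean of each gene's probe sets, 4.96 and -2.02), and 20 genes did not pass. The list as a whole was not called (median 0.02, camera adjusted p = 0.905). These genes are remembered from the study's paper on these arrays and are not independent evidence.

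Of the usual heart failure genes, NPPB, the natriuretic peptide B gene, differed by 3.89 (SE 1.87, limma adjusted p = 0.496), with values of 3.63 and 5.91 on affected 1 and affected 3 and -1.21 on affected 2. Its difference was 2.32 without affected 3, 5.88 without affected 2 and -0.095 for affected 2 against the controls alone. MYH7, the beta myosin heavy chain gene, differed between -0.36 and 0.31 over its 5 probe sets. The calcium pump ATP2A2 differed by -0.48 (SE 0.79), which ran from -1.08 without control 2 to 0.48 without control 1, and by 0.083 in a probe set left out by range. Its inhibitor PLN differed by -0.04, 0.03 and 0.52, the last of which turned to -0.26 for affected 2 alone, and the release channel RYR2 by -0.57 and 0.02. With single arrays left out, that PLN value was 0.25 without affected 1 and 0.91 without affected 2, and the first RYR2 value was -1.01 without control 2, -0.29 without control 1 and -0.36 without affected 1. None of them passed the adjusted threshold. No probe set was named here for NPPA, MYH6, CASQ2, XIST or a Y-linked gene, so the recorded sexes could not be checked.

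Genes of the extracellular matrix and fibrosis list rose as a group in affected hearts, with 38 of 45 genes above 0 and a median of 0.71 (camera adjusted p = 9.93e-08 with the preset correlation, adjusted p = 0.926 with an estimated correlation). Adjusted over the list alone 2 passed, the Wnt antagonist FRZB at 2.65 (SE 0.34, limma adjusted p = 0.00421) and MFAP4, a microfibril protein, at 2.29 (SE 0.47, limma adjusted p = 0.0394), and 0 passed over all genes. POSTN at 2.93 and SFRP1 at 1.29 came next. Fibroblast markers rose as a group too, 11 of 14 above 0 with a median of 0.87 (camera adjusted p = 0.00274, adjusted p = 0.737 with an estimated correlation), with COL1A1 at 1.75, FBLN1 at 1.49, COL3A1 at 1.77 and LUM at 1.76, and 0 passing over the list alone. These named genes and several other fibroblast markers are also in the matrix list, so the rise of the fibroblast list is not a separate result. Endocardium and valve markers rose by a median of 0.97 over 7 genes (camera adjusted p = 0.00274, adjusted p = 0.391 with an estimated correlation), and CILP at 3.47, CDH11 at 1.99 and SMOC1 at 1.38 passed adjusted over the list alone, with COMP at 0.83 next.

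The matrix genes moved with the arrays whose spiked control transcripts stood apart, affected 1 and affected 3. The list's median value on these arrays was 0.84 and 0.66, against -0.09 on affected 2 and 0.09, -0.21 and -0.66 on the controls. The 3' minus 5' difference of the beta-actin and GAPDH control probe sets, higher where RNA integrity is lower, ran alike in part. It was 0.17 and 0.27 on affected 1 and affected 3, -0.02 on affected 2 and 0.02, 0.13 and -0.24 on the controls. This came from beta-actin (0.31 and 0.58 on affected 1 and affected 3), while the GAPDH values there were 0.02 and -0.03 and its highest were 0.15 on control 2 and 0.14 on affected 2. With a term for these arrays, an alternative chosen after seeing the data, the comparison rested on affected 2, 1 dog, against the 3 controls, and that dog was assumed to vary like the others. The median was then 0.11 for the matrix list (camera adjusted p = 0.109) and was 0.47 for fibroblast markers (camera adjusted p = 0.104), while endocardium and valve markers had a median of 0.90 (camera adjusted p = 0.0158). Without a filter, and with 13 genes measured, the endocardium and valve list had a median of 0.00 (camera adjusted p = 0.148), and after quantile normalization its median was 0.56. With 1 array left out, these 3 lists kept their camera calls with the preset correlation in all 6 fits. The matrix median then ran from 0.50, without control 3, to 1.02.

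**Figure D2:**
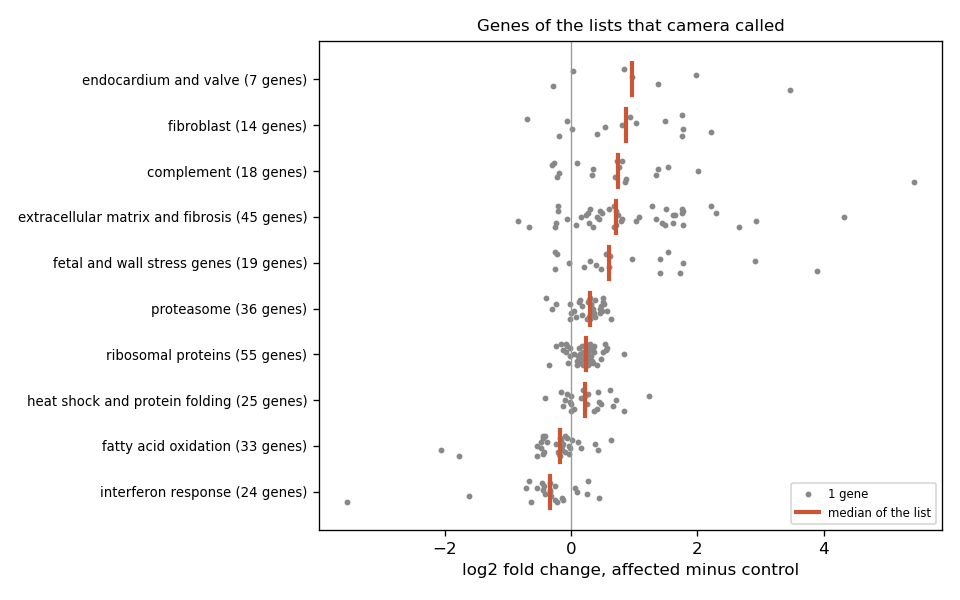
Log2 fold change, affected minus control, of each gene (grey points) in the 8 gene lists and 2 marker lists that camera called with the preset correlation, with the median of each list as an orange line. Medians run from 0.97 for endocardium and valve to -0.33 for the interferon response.

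Fetal and wall stress genes also rose as a group, with a median of 0.61 over 19 genes (camera adjusted p = 0.000204, adjusted p = 0.926 with an estimated correlation). TNNT1, the slow skeletal troponin T, at 1.41, the atrial light chain MYL7 at 1.41, the stretch-responsive ANKRD1 at 0.61 and CLU (clusterin) at 1.53 had the smallest p, and 0 passed over the list alone. Proteasome subunits were higher by a median of 0.31, 31 of 36 above 0 (camera adjusted p = 0.000183, adjusted p = 0.926 with an estimated correlation), with PSMC2 at 0.63, PSMA4 at 0.52, PSMD2 at 0.46 and PSMB1 at 0.51. Ribosomal proteins were higher by a median of 0.24, 45 of 55 above 0 (camera adjusted p = 0.000515, adjusted p = 0.926 with an estimated correlation), with RPL35 at 0.42 and RPL9 at 0.55. Heat shock genes had a median of 0.23 over 25 genes (camera adjusted p = 0.0371, adjusted p = 0.926 with an estimated correlation), led by the small heat shock genes HSPB2 at 0.83 and HSPB3 at 1.23. Complement genes had a median of 0.74 over 18 genes (camera adjusted p = 0.0491, adjusted p = 0.926 with an estimated correlation). In this list C6 passed adjusted over the list alone at 5.42 (SE 0.84, limma adjusted p = 0.00584), followed by CLU at 1.53, CFD at 1.35 and C7 at 0.81. With the term for affected 1 and affected 3, which left 1 affected dog against the 3 controls, none of the 5 lists was called, and the medians were 0.17, 0.18, 0.01, 0.06 and -0.29.

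The heat shock and complement calls ended when single arrays were left out. Heat shock genes had a camera adjusted p of 0.278 without control 2 (median 0.24) and 0.378 without affected 3 (median 0.10). It was 0.0628 in the upper 50% by range (median 0.27), 0.0593 after quantile normalization (median 0.17), 0.0503 with sex (median 0.23) and 0.078 with age (median 0.25). Complement genes had a camera adjusted p of 0.464 without control 2 (median 0.47), 0.169 without control 3 (median 0.40) and 0.465 without affected 1 (median 0.14). The median was 1.23 without control 1 and 1.15 without affected 2. Their call also ended after quantile normalization (0.142, median 0.45), after median centring (0.073, median 0.77), with sex (0.0503, median 0.74) and with the largest-range probe set per gene (0.0753, median 0.84). The complement values were 1.52 on affected 1, -0.19 on affected 2 and 0.19 on affected 3, against 0.58, -0.47 and -0.64 on the controls. Macrophage and monocyte markers ran alike over the arrays, at 2.04, -0.09 and 0.09 on the affected and 0.77, -0.36 and -0.37 on the control arrays. The lists share 3 genes, and without these the complement values were 1.16, -0.27 and 0.50 on the affected and 0.27, -0.53 and -0.47 on the control arrays. Ribosomal proteins had a median of 0.15 without affected 1. With a range of at least 1, which left 12 ribosomal, 16 proteasome and 12 heat shock genes, the camera adjusted p was 0.593, 0.88 and 0.364, while the medians were larger, at 0.40, 0.39 and 0.53.

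Interferon response genes fell as a group in affected hearts, 19 of 24 below 0 with a median of -0.33 (camera adjusted p = 0.014, adjusted p = 0.926 with an estimated correlation). CXCL10 passed adjusted over the list alone at -3.54 (SE 0.40, limma adjusted p = 0.000988), and CMPK2 at -0.53, IFI44 at -1.62 and PARP9 at -0.66 came next. Control 2 held the highest list value, 1.05, against -0.05 and 0.04 on control 1 and control 3 and 0.06, -0.16 and -0.04 on the affected arrays. Without control 2, the female control, the median was 0.02 (camera adjusted p = 0.998), so the fall of the list rested on that array. The median was -0.52 without control 1, and the call also ended without affected 2 (camera adjusted p = 0.0593, median -0.25) and without a filter (camera adjusted p = 0.131, median -0.24). With the term for affected 1 and affected 3 it was the 1 gene list called (camera adjusted p = 0.00831, median -0.46), again from 1 affected dog. Fatty acid oxidation genes fell by a median of -0.17, 27 of 33 below 0 (camera adjusted p = 0.0356, adjusted p = 0.926 with an estimated correlation), with PDK4, the inhibitor of pyruvate dehydrogenase, at -1.78, MLYCD at -0.47 and SLC27A6 at -0.41, while ACAA1 was at 0.43. This call ended without control 2 (camera adjusted p = 0.372, median -0.12) and without affected 1 (camera adjusted p = 0.0796, median -0.20). It ended too without a filter (camera adjusted p = 0.613, median -0.17), with age (camera adjusted p = 0.078, median -0.16) and with the term for affected 1 and affected 3 (camera adjusted p = 0.28, median -0.15).

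The other 25 gene lists were not called, with adjusted p from camera between 0.0975 and 0.995. Muscle structure lists had medians of 0.19 for the sarcomere, 0.33 for the dystrophin complex and cytoskeleton, where SGCE (epsilon sarcoglycan) at 2.18 passed adjusted over the list alone, and 0.07 for the intercalated disc. Energy lists had medians of -0.06 for respiratory complex I, 0.06 for complexes II to V, -0.12 for the tricarboxylic acid cycle, 0.19 for glycolysis with ALDOC at 1.68 passing over the list alone, -0.12 for ketone and branched chain amino acid use with MCCC2 at -1.15 passing over the list alone, and 0.07 for creatine and energy transfer. Signalling lists had medians of 0.00 for adrenergic signalling, 0.08 for renin-angiotensin and natriuretic signalling, 0.07 for ion channels, -0.01 for insulin-like growth factor and hypertrophy signalling and -0.01 for angiogenesis. Stress lists had medians of 0.06 for immediate early genes, 0.15 for endoplasmic reticulum stress, 0.06 for ubiquitin ligases and autophagy, 0.05 for oxidative stress defence, 0.13 for hypoxia and 0.02 for apoptosis. Immune and other lists had medians of 0.14 for antigen presentation, 0.03 for cytokines and inflammation, -0.06 for the cell cycle and -0.22 for the circadian clock. In 9 of these lists the direction given by camera, the median and the mean did not all have one sign.

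Markers of the other cell types were tested in 10 further lists, none of them called by camera, while fry's test for change in either direction called atrial myocyte and nerve and Schwann cell markers (adjusted p = 0.0196 for each). Cardiomyocyte markers had a median of 0.19 (camera adjusted p = 0.269), atrial myocyte markers 0.04, endothelial markers -0.31 (camera adjusted p = 0.132), smooth muscle and pericyte markers -0.04 and adipocyte markers 0.42. Macrophage and monocyte markers had a median of 0.74 with 16 of 18 above 0 (camera adjusted p = 0.0599). T and NK cell markers had a median of -0.23 (camera adjusted p = 0.0599), B and plasma cell markers -0.21 (camera adjusted p = 0.0613), nerve and Schwann cell markers -0.15 with PMP22 at 0.89 passing adjusted over the list alone, and skeletal muscle markers -0.16 with TNNT1 at 1.41 passing adjusted over the list alone. In 1 of these lists, skeletal muscle, the mean and the median had opposite signs. TNNT1 did not pass adjusted over the fetal and wall stress list alone. T and NK cell values were 0.16, 0.02 and 0.48 on the controls and -0.02, -0.02 and -0.04 on the affected arrays. B and plasma cell values were 0.31, 0.04 and 0.29 on the controls and -0.04, -0.09 and -0.04 on the affected arrays. The unexpressed tags also lay lower on affected arrays, and lowest among controls on control 2. A background offset was therefore not told apart from lower marker levels. Another 7 marker lists had under 5 measured genes and were not tested. They held S100A8 at -2.14 and S100A9 at -2.71 with CAMP at -0.36 for neutrophils, IRX3 at -2.58 with PCP4 at -0.23 and SCN10A at 0.14 for the conduction system, ALAS2 at -1.52, HEMGN at -0.58, CA1 at -0.44 and LOC480784 at 0.15 for erythrocytes, PPBP at -1.04 and NRGN at -0.32 for platelets, CPA3 at 0.40, HPGDS at -0.42 and GATA2 at -0.01 for mast cells, KRT18 at 0.83, KRT8 at -0.37, KRT7 at -0.15 and MUC16 at -0.13 for mesothelium, and no gene for XIST and the Y chromosome.

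The 3' minus 5' difference, higher where RNA integrity is lower, was -0.03 ± 0.19 (SD, n = 3) in controls and 0.14 ± 0.15 (SD, n = 3) in affected hearts. The groups thus differed by 0.17 (exact permutation test, two-sided, p = 0.4, where 0.1 is the smallest p possible). The probe sets of unexpressed tags lay lower on affected arrays by 0.093. Their groups did not overlap either, at 0.06, 0.01 and 0.13 on the controls and -0.03, -0.03 and -0.01 on the affected arrays. No probe set had a group difference that differed between the sexes at the adjusted threshold in limma, where 2328 did at an unadjusted p under 0.05 and 1288 would be expected by chance. With 1 female per group and 2 residual degrees of freedom this says nothing on whether the sexes differed.

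**Figure D3:**
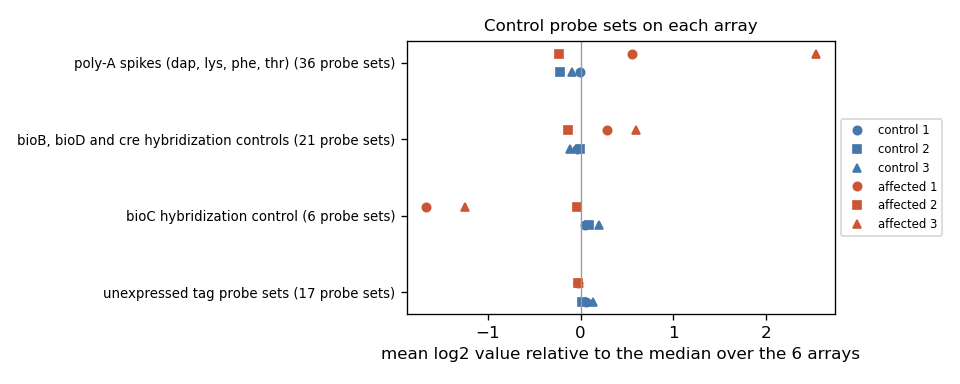
Mean log2 value of 4 sets of control probe sets on each array relative to the median over the 6 arrays (horizontal axis), controls in blue and affected in orange. Affected 3 stands at 2.53 and affected 1 at 0.55 for the poly-A spikes, and both lie at -1.25 and -1.66 for bioC, while affected 2, at -0.23 and -0.04, lies just below the lowest control (-0.22 and 0.05).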

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

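The tests on cell type medians, on the array batch, on the triadin probe sets and on the offset of unexpressed probe sets were chosen only after the result was seen; quantile normalization, leaving out single arrays and the splits had been planned, but were read as tests of these patterns only after their values were seen. The array's control transcripts, which are not dog genes, were left out of the comparisons and on affected 1 and affected 3 their poly-A spikes and their bioB, bioD and cre controls lay above every control array. The poly-A spikes averaged 2.53 on affected 3, 6.23-fold over the control mean, and 0.55 on affected 1, 1.58-fold over it. The bioB, bioD and cre controls averaged 0.59 on affected 3 and 0.29 on affected 1. The bioC control went the other way, at -1.66 on affected 1 and -1.25 on affected 3. On affected 2 the same 3 sets of controls averaged -0.23, -0.13 and -0.04, each below the lowest control (-0.22, -0.11 and 0.05).

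The higher matrix and fibroblast genes in affected hearts are the first pattern that was weighed. If a lower share of cardiomyocytes left the other cell types in unchanged proportion, the markers of all of these would rise alike. The fibroblast median lay 1.18 above the endothelial median (95% bootstrap interval over genes, not dogs, 0.42 to 1.96). Such an interval does not cover the spread between dogs, so this test leaves that case open. The endothelial values were -0.06, 0.50 and 0.04 on the controls and -0.46, -0.04 and 0.23 on the affected arrays. Fibroblasts in place of cardiomyocytes would also put fibroblast markers above endothelial ones, so a changed tissue makeup stays open. Quantile normalization gives all arrays the same distribution of values. After it the matrix list kept a median of 0.51 and was still called by camera with the preset correlation. This argues against array scaling of the whole distribution only. Scaling that depends on expression level stays open, since the deposited values hold no level. A batch shared by affected 1 and affected 3 stays open, because the matrix median of affected 2, 1 dog, against the controls was 0.11, and so does RNA quality, where the 3' minus 5' difference was highest on those arrays for beta-actin and not for GAPDH. Differences between the animals in disease or breed stay open too and were not tested.

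For triadin, probe sets of the same gene went different ways. If the 3 flat probe sets measured only background, they would follow the unexpressed tag probe sets, and their highest correlation with the tags over the 6 arrays was 0.20. Of the probe sets left out by range, 6.74% fell that low or lower, so this test leaves background open. Breed variants under the probes of the 5 lower probe sets may also contribute and cannot be told apart from a lower transcript level without the probes' sequences. Lower transcript levels or transcript forms in affected dogs stay open as biology and were not tested.

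The interferon response genes, lower in affected hearts, are the third pattern that was weighed. The unexpressed probe sets lay lower in affected arrays by 0.093. Without the 1 member that followed the tags the list's median was -0.33 (95% bootstrap interval over genes -0.42 to -0.22). An interval over genes does not cover the spread between dogs, so this test leaves the offset open. Array scaling of the whole distribution of values is argued against, with a median of -0.45 after quantile normalization. Scaling that depends on expression level stays open. The list's difference rested on a single control array, since without control 2 the median was 0.02. Disease and breed stay open and were not tested.

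The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6 higher probe sets at the adjusted threshold against at most 2 in one direction of another split, and 0 lower. In the other splits higher and lower have no meaning, so each count was set against the larger of their directions. It gave 663 higher probe sets by the looser criterion against at most 499 (control 1 with affected 1 and affected 3, the arrays whose spiked controls stood apart), and 198 lower, where 5 splits, the real one included, had 198 or more in one direction. For gene lists it gave 8 against at most 14, and 4 splits gave 8 or more. For marker lists it gave 2 against at most 5, and 5 splits gave 2 or more. Splits with a count as large, the real one included, numbered 1 for each count of higher probe sets, 5 for the lower ones by the looser criterion and 10 for the lower ones at the adjusted threshold.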

How the results depend on the processing

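Counts moved with most settings, and the cause was not tested except where stated; the terms for affected 1 and affected 3, affected 2 alone, the variance trend, the range of at least 1 and the largest-range probe set were chosen after seeing the data. The planned pseudocount was not run. At the adjusted threshold (6 higher, 0 lower) the counts were 1 higher without a filter, 2 lower in the upper 50% by range, 0 higher after quantile normalization, 3 higher with sex, 3 higher and 1 lower with age, 1 lower with a variance trend, 68 higher and 23 lower with a range of at least 1 (10128 probe sets tested), 1 higher with the term for affected 1 and affected 3 and 0 higher for affected 2 alone, where fewer arrays remain. Leaving out 1 array gave 1 to 7 higher and 0 to 5 lower, 311 to 1150 higher and 144 to 367 lower by the looser criterion, 4 to 12 gene lists and 2 to 4 marker lists. With age 302 were lower by the looser criterion. The fit of array weights stopped with a warning before convergence, giving control 1 a weight of 50.3, and their 3903 higher and 3972 lower calls, 1198 higher and 676 lower by the looser criterion, 3 gene lists, 0 marker lists and complement median of -0.076 are void.

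The replicate numbers are those of different dogs, and same-numbered arrays deviated together with correlations of 0.27, 0.15 and 0.02, so they were not taken as pairs; control 3 correlated best with affected 2. The replicate block gave 12 higher and 4 lower probe sets, FKBP1B, C6, IGSF1, MYOT, KIF23 and CXCL10 among them (limma adjusted p from 0.00969 to 0.0405), and ended the heat shock call (camera adjusted p = 0.0569).

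Gene lists called (8) and marker lists called (2) became 0 and 0 with an estimated correlation and with fry's directional test (0 and 3 with its mixed test), 1 and 1 with the term for affected 1 and affected 3 and for affected 2 alone. Marker lists were 5 without a filter, 4 with age and 4 with a range of at least 1. With that term, and for affected 2 alone, complement turned to -0.29, ribosomal proteins ended at 0.010 and ranked below other genes, NPPB turned to -0.095 and PLN to -0.26. ATP2A2 ran from -1.08 to 0.48 with 1 array left out, turning without control 1, and MYH7 to -0.038 as the mean of its probe sets. The 3' minus 5' value was higher in affected hearts by 0.05 to 0.29 under its alternatives and kept its sign for either transcript alone. Of 520 values of named genes under the alternatives other than array weights, 473 kept direction and side of the threshold, 10 (all of EPYC) lost it, 31 passed it (18 of them with a range of at least 1) and 6 turned. Of 200 list values 139 kept both, 57 lost the threshold and 4 turned. The term for affected 1 and affected 3 and affected 2 alone are counted apart but give the same log2 changes, those of 1 affected dog. Signal over background is not known from these values.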

Other observations

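Several single genes not yet described differed without overlap between affected and control hearts, and were chosen after their values were seen. Of all tested probe sets 32.5% did not overlap, so this does not set these genes apart. IRX5, a transcription factor of the family of IRX3, was lower on all 3 affected arrays by -1.70 (SE 0.28, n = 3 and 3, limma adjusted p = 0.25). The chemokines CCL21 and CXCL12 were higher by 1.83 (SE 0.31) and 1.30 (SE 0.29), and both passed adjusted over the cytokine list alone (limma adjusted p = 0.0162 and 0.039). CDK1, the mitotic kinase, was higher by 2.77 (SE 0.43) and AURKB by 2.23 (SE 0.68), while the mitotic KIF23, named above, was lower by -2.91 (SE 0.55) on the mean of its probe sets. MFN2, which fuses mitochondria, was lower by -1.97 (SE 0.48), GPX3 by -1.19 (SE 0.27), and EDN1, the endothelin 1 gene, was higher by 0.98 (SE 0.24). None of these genes passed over all genes tested.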
